A study of Mus musculus with 6 samples.

How the data were processed

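Gene expression was measured on 6 Affymetrix mouse arrays hybridised with RNA from sorted retinal cells of C57BL/6 mice at postnatal day 6. Per the labels, retinas were dissociated with papain, cells were sorted by flow cytometry, and RNA was amplified in 2 rounds before biotin labelling. The cells form 3 groups of 2 arrays each. Cells positive for both GFP and Thy1 came from the Hb9 line and from the Drd4 line, and Thy1-positive cells form the reference group. The series text states that both replicates of a group came from different litters.

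The deposited values are probe set intensities on a linear scale. The software, the background correction, the summarisation and the normalisation behind these deposited intensities are not given in the sources used here. Of the 45101 probe sets in the table, 64 are controls, 34945 map to 1 gene, 932 map to several genes and 9160 have no gene named. Genes were named with the probe annotation, and 34741 probe sets were matched to the mouse RefSeq gene table by Entrez identifier, which changed 0 symbols. Positions are not given because the annotation was used for names only. No value was at or below 0, so no floor was applied before log2 was taken. For each gene the probe set with the highest mean log2 intensity over the 6 arrays was kept, which left 18193 genes.

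The groups were compared with limma 3.58.1 in R 4.3.3. A mean was fitted to each of the 3 groups, with 3 residual degrees of freedom, and the spread was moderated across genes with an intensity trend. The prior had 6.98 degrees of freedom. Hb9 was compared with Thy1, Drd4 with Thy1, Hb9 with Drd4, and the mean of both GFP lines with Thy1. All tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 18193 genes at a threshold of 0.05. The number of arrays limits the precision, and the median standard error of a log2 difference between single groups was 0.15. An exact permutation test of 2 arrays against 2 cannot give a p below 0.333, so no single gene was tested that way. Groups of 2 are too small for a test of outlying arrays and for a count over other splits of the samples.

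The comparisons, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The 32 lists cover retinal cell types, cell states and families of neuronal genes. Each was tested with camera in limma at a preset correlation between genes of 0.01, and again with an estimated correlation. The estimate rests on 3 residual degrees of freedom, which leaves that form little power. A list that fails under it is not shown to be unchanged. The preset treats the genes of a list as nearly independent, so its p-values can be too small for genes that move together. The p-values of camera were adjusted over the lists within a comparison. Counts of list members are after adjustment over all genes, and for most lists described the count after adjustment over the list alone is given too. Some list genes have no probe set of their own and were not analysed here.

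The rule for named genes took 4 kinds of genes in each comparison. The first are the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold whose groups do not overlap, passing over clone and model names. The next are up to 3 members of each list past the threshold with the largest differences. A fixed set of 8 genes, namely Thy1, Mnx1, Drd4, Cartpt, Mmp17, Cdh6, Col25a1 and Fstl4, was taken whatever the test gave. The last are 8 genes that changed against Thy1 in the same direction in both lines and 4 that changed in opposite directions, each ranked by the smaller in size of their log2 differences in Hb9 and Drd4. A comparison with fewer than 6 genes past the threshold would have added the 8 genes with the smallest p, which did not occur. Members of a list that are named only to spell out a small count stand outside this rule and were read off after their values were seen.

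The alternatives were quantile normalisation, centring of each array on its median, the mean of all probe sets of a gene, dim genes left out, moderation without the trend or with robust settings, array weights, and the replicate number as a block. They also included an offset of 16 before log2, a minimum of 1 on the log2 scale, only the compared groups in the model, an estimated correlation for the list tests, and each array left out in turn. A count without the genes of the cell type and cell state lists was added after the data were seen. The replicate numbers are not stated to mark a shared litter, so they did not enter the model.

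Both comparisons with Thy1 share the Thy1 arrays. Their overlap was set beside 100 simulated data sets in which unchanged groups met the same kind of shared reference. The procedure was also tested on simulated data with 200 changed genes among 18193 in 5 runs. Against Thy1, 8.40% of simulated changes of 0.50 on the log2 scale were recovered in Hb9, 93.6% of changes of 1 and 100% of changes of 2, with 6.40 false calls per run. The simulated noise was drawn separately for each gene, without effects shared by all genes of an array. These rates may therefore not hold for the real arrays. The files hold no detection calls. As a background reference, chosen after the data were seen, each array's highest intensity among 27 bacterial control probe sets was used, at 4.95 to 5.38 on the log2 scale. Where a group's mean lay at or below it, the difference is given as at least the fold over the higher of value and reference on each array, also where 1 of the 2 arrays lay above it. Plots were drawn with matplotlib 3.10.9.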

Results

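Sorted retinal ganglion cells (RGCs), the output neurons of the retina, were profiled at postnatal day 6 on 6 arrays, 2 for each of 3 groups. The Hb9 and Drd4 groups hold cells positive for GFP and Thy1 from 2 mouse lines. Each line is known to label a type of ON-OFF direction-selective ganglion cell (ooDSGC). The Thy1 group holds cells stained for Thy1, a surface protein found on RGCs in general. The median intensity of the arrays ranged from 45.5 to 47.7, and intensities ran from 5.54 to 13187. Of the 18193 genes, 68.2% to 78.9% per array lay above the highest bacterial control. Across genes, which are not independent replicates, log2 intensities of replicate arrays correlated at 0.992 in Hb9, 0.988 in Drd4 and 0.990 in Thy1. Arrays of different groups correlated at 0.963 to 0.981. Errors of log2 differences are standard errors from limma, errors of intensities are SD, and n = 2 arrays in each group throughout.

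The genes that give the lines their names passed in no comparison. Mnx1, which encodes Hb9, was at or below the background reference in all 3 groups, with mean log2 intensities of 3.95 in Hb9, 4.07 in Drd4 and 3.95 in Thy1. Drd4, a dopamine receptor, stood at 5.54 ± 0.01 in Hb9, 5.56 ± 0.38 in Drd4 and 5.62 ± 0.33 in Thy1. A second probe set of this gene differed by 0.55 as Drd4 minus Thy1 and by -0.46 as Hb9 minus Drd4, and did not pass. Thy1 itself was bright in every group, at 11.58 ± 0.11, 11.76 ± 0.03 and 11.24 ± 0.0043. It was higher in Drd4 than in the Thy1 sort by 0.52 ± 0.10 on the log2 scale (adjusted p = 0.0149 in limma). That call was lost without Drd4 replicate 2 (adjusted p = 0.0841) and without either Thy1 replicate (adjusted p = 0.0601 without replicate 1 and 0.0545 without replicate 2), and with moderation without the trend (0.0542). In Hb9 the Thy1 difference of 0.34 ± 0.10 did not pass (adjusted p = 0.0826).

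**Figure D1:**
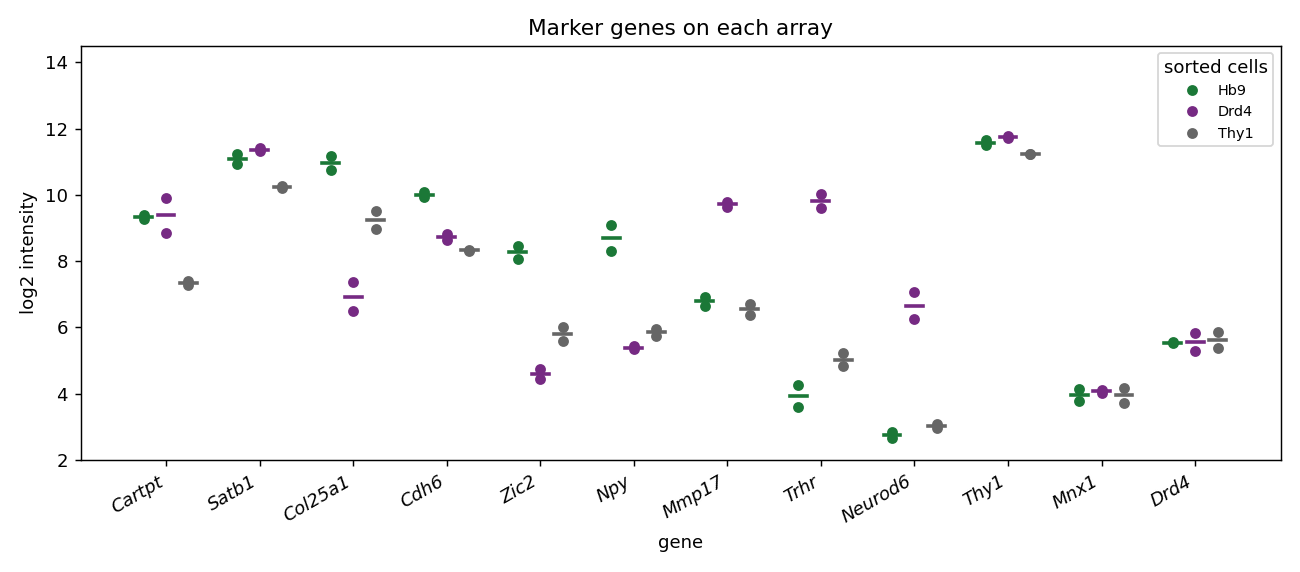
Log2 intensity (vertical axis) of 12 genes (horizontal axis) on each array, with points for arrays and bars for the means of the 2 arrays of a group. Trhr is at 9.82 in Drd4 against 5.03 in Thy1 and 3.93 in Hb9, and Zic2 is at 8.26 in Hb9 against 5.80 in Thy1 and 4.59 in Drd4.

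The comparison of Hb9 with Thy1 asks which genes set Hb9 cells apart from the Thy1 sort. Most microglial genes and several pericyte genes read higher in that sort, as given below. For a single gene lower in Hb9, other cells in the sort are not separated from a difference between RGCs. Hb9 cells had 3.96-fold more transcript of Cartpt, a neuropeptide precursor used as an ooDSGC marker, than the Thy1 sort (log2 difference 1.99 ± 0.27). They also had more Npy, another neuropeptide (2.85 ± 0.23, 7.21-fold), more of the transcription factor Zic2 (2.47 ± 0.20, 5.53-fold), and more Cdh1, the gene of E-cadherin (2.51 ± 0.19, 5.71-fold). Cbln4, a secreted synaptic organiser, was 5.04-fold higher, and the retinoic acid binding protein gene Crabp2 was 3.77-fold higher. Eya1, a transcriptional cofactor, was 3.91-fold higher. Myh1, a myosin heavy chain gene, was at the background reference in Thy1 and at least 3.77-fold higher in Hb9. Lower in Hb9 was Ahnak (-3.54 ± 0.37), where 1 of 4 probe sets passed. With Hb9 means at the background reference, Col3a1 (lower by at least 3.33 on the log2 scale) and Aspn (at least 3.53-fold) were lower too. Also lower were Jag1, a Notch ligand (-3.02 ± 0.39), the phosphodiesterase gene Pde5a (-3.03 ± 0.42) and the transcription factor gene Sall1 (at least 8.91-fold), whose call was lost with robust moderation (adjusted p = 0.0685).

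Of 5 ooDSGC genes put forward by the group that made these data, 3 rose in Hb9, namely Cartpt, Cdh6 (1.67 ± 0.15) and Col25a1 (1.72 ± 0.28), and adjusted over the list alone 3 rose too. Whether the list was drawn up on these arrays is not given in the sources used here, so its direction is not taken as independent evidence. Its camera test in limma gave an adjusted p of 0.000594, and an adjusted p of 0.376 with an estimated correlation. Mmp17 (0.24 ± 0.18) and Fstl4 (0.12 ± 0.13) did not pass. Among 7 other ooDSGC genes, Cntn5 (1.40 ± 0.18) and Satb1 (0.86 ± 0.13) rose and Trhr fell, with 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.497). The Satb1 call was lost without Hb9 replicate 2 (adjusted p = 0.0537). The Trhr call was lost in 5 alternatives, among them without Hb9 replicate 1 (adjusted p = 0.181) and without either Thy1 replicate (adjusted p = 0.0576 and 0.0875), and both group means lie at or below the background reference.

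Of 22 markers of other RGC types, 7 fell in Hb9, 1, Zic2, rose and 14 did not pass, or 11 and 2 adjusted over the list alone. Eomes, a transcription factor of melanopsin-containing RGCs, fell by 2.35 on the log2 scale, to 6.23 ± 0.11 from 8.58 ± 0.15, and Tbx20 was at least 2.74-fold lower. Among 67 neuronal transcription factors 13 fell and 4 rose, or 19 and 7 adjusted over the list alone. Camera gave adjusted p-values of 1.08e-05 and 0.000183 for these 2 lists, and adjusted p = 0.376 for both with an estimated correlation. With Hb9 replicate 1 left out, 2 markers of other RGC types and 4 transcription factors passed as lower, and without Thy1 replicate 1 the counts were 4 and 5.

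Genes of neurotransmission and cell contact went both ways in Hb9. Nicotinic acetylcholine receptor genes that rose were Chrna3 (1.69 ± 0.18), Chrnb4 (1.21 ± 0.17) and Chrna5, while Chrna6 and Chrna4 fell. They were counted among 12 measured cholinergic receptor genes, a list that also holds muscarinic receptors. GABA and glycine receptor genes had 5 of 16 higher, led by Gabra5 (1.30 ± 0.16), and 0 lower. Of 21 glutamate receptor genes the kainate receptor gene Grik1 rose (1.45 ± 0.19). Among 37 cadherins and protocadherins 7 rose and 5 fell, with Fat1 (-1.34 ± 0.19) and Cdh11 (-1.25 ± 0.18) among the lower ones. Among 59 immunoglobulin and leucine-rich recognition proteins 7 rose and 4 fell, with Lrrtm2 at -1.98 ± 0.26. Among 64 axon guidance genes 4 rose and 3 fell, with Unc5d at -1.53 ± 0.15 and Sema5a at least 2.60-fold lower. Adjusted over the list alone, the counts higher and lower were 3 and 2, 5 and 1, 1 and 0, 9 and 6, 7 and 4, and 9 and 4 in that order. None of these lists passed camera, whose adjusted p-values ran from 0.391 to 0.993. Without Hb9 replicate 2 there were 2 GABA and glycine receptor genes, 2 cadherins, 1 recognition protein and 1 guidance gene higher, and without Thy1 replicate 1 there were 2, 3, 2 and 1. With Hb9 replicate 1 left out they numbered 3, 2, 2 and 2, and 3 cadherins, 1 recognition protein and 0 nicotinic receptor genes were lower.

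Of 14 microglial genes, 13 fell in Hb9 against the Thy1 sort, with a median log2 difference of -2.34, and 14 were lower adjusted over the list alone. C1qa, a complement gene, fell by 2.79 on the log2 scale (6.93-fold), and Csf1r, a receptor of microglia and macrophages, was 5.60-fold lower. Of 17 genes of dividing cells 6 fell (11 adjusted over the list alone), among them Top2a, at least 2.84-fold lower. Of 20 immediate-early and dissociation genes 8 fell (12 over the list alone), among them Egr1 at -1.53 ± 0.26, and of 14 endothelial and pericyte genes 4 fell (6 over the list alone), among them Kcnj8, at least 3.61-fold lower. Camera adjusted p-values were 3.82e-17, 1.54e-09, 3.23e-10 and 0.000328 in that order. With an estimated correlation the adjusted p-values were 0.376, 0.376, 0.416 and 0.376. Without Thy1 replicate 1 the lower genes numbered 5 microglial, 7 cell cycle, 1 immediate-early and 2 vascular, and without Hb9 replicate 1 they numbered 6, 3, 0 and 3. Without Hb9 replicate 2 they numbered 10, 2, 2 and 2. With robust moderation 7 microglial genes passed. Csf1r was lost without Thy1 replicate 1 (adjusted p = 0.0598) and with robust moderation (adjusted p = 0.0706), and Egr1 without Hb9 replicate 1 (adjusted p = 0.0626) and Thy1 replicate 1 (adjusted p = 0.0598).

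Few list members of other cell types passed. No member of the amacrine (12 measured), starburst amacrine (5), rod (15), cone (11), astrocyte (6), erythrocyte (3) or myelin (7) lists passed, and the same held for 30 synaptic vesicle genes and 18 genes of retinal position. Of 16 genes of Muller glia and progenitors Apoe (-2.56) and Vim (-2.08 to -1.45 over its 3 probe sets) fell. Septin4 (-1.38 to -1.19 over its 2 probe sets) fell among 6 horizontal cell genes. Among 19 pan-RGC genes Nefm rose and Chrna6 fell. The horizontal cell list passed camera (adjusted p = 0.048, and adjusted p = 0.376 with an estimated correlation). The Apoe call was lost without Thy1 replicate 1 (adjusted p = 0.0517) and with robust moderation (0.0590), the Nefm call without Hb9 replicate 1 (0.215) or either Thy1 replicate (0.0700 and 0.0547), and the Chrna6 call without Hb9 replicate 1 (0.0700).

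In all, 1220 genes differed between Hb9 and Thy1, 640 higher and 580 lower, and 403 of them by at least 2-fold. The count was 315 without Hb9 replicate 1, 441 without Hb9 replicate 2 and 380 without Thy1 replicate 1. Which direction holds more genes is not settled, since quantile normalisation gave 457 higher and 579 lower, the 2-fold minimum 106 and 297, and these left-out arrays 96 and 219, 141 and 300, and 121 and 259.

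The comparison of Drd4 with Thy1 asks the same of Drd4 cells. Their largest rise was in Trhr, the receptor of thyrotropin-releasing hormone, at 9.82 ± 0.29 against a Thy1 mean at background of 5.03 ± 0.27 (at least 24.8-fold). Mmp17, a membrane-bound metalloproteinase gene, was 8.93-fold higher (3.16 ± 0.18), and Cartpt was 4.11-fold higher (2.04 ± 0.27). Higher too were Oxtr, the oxytocin receptor (2.87 ± 0.15), the cadherin gene Cdh7 (2.57 ± 0.20), Kctd4 (2.92 ± 0.16) and Ndrg1 (2.59 ± 0.20). Against Thy1 means at background, Col24a1 was at least 4.87-fold, the potassium channel gene Kcna5 at least 4.07-fold and the transcription factor gene Neurod6 at least 2.87-fold higher. Among the largest falls were Epas1 (-4.32 ± 0.40), S1pr3 (-4.26 ± 0.36) and, with Drd4 means at background, Jag1 (at least 23.3-fold) and Nid1 (at least 15.0-fold). Pdgfrb (at least 18.5-fold), Rgs5 (-5.23 ± 1.02) and Abcc9 (-4.55 ± 0.52), which are known from pericytes, were lower as well. On Drd4 replicates 1 and 2 they read 5.93 and 3.14, 9.50 and 5.01, and 6.77 and 4.54, so their sizes depend on the replicate. With robust moderation the last 3 calls were lost (adjusted p = 0.109, 0.356 and 0.0565), and Rgs5 was also lost without either Thy1 replicate (adjusted p = 0.0675 and 0.0735).

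Of the 5 ooDSGC genes from the study's own group, Mmp17 and Cartpt rose and Col25a1 fell by 2.30 on the log2 scale. Cdh6 (0.40 ± 0.15) and Fstl4 (0.30 ± 0.13) did not pass over all genes, and adjusted over the list alone 4 rose and 1 fell, which is again not independent evidence. Of 7 other ooDSGC genes, Trhr and Satb1 (1.14 ± 0.13) rose and Calb1 fell by 1.82, with 4 higher and 2 lower adjusted over the list alone. Camera gave adjusted p-values of 0.00995 and 0.0262, and adjusted p = 0.257 for both lists with an estimated correlation.

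Of 22 markers of other RGC types 12 were lower in Drd4 and 0 higher (13 and 1 adjusted over the list alone). Zic1 fell by 4.14 on the log2 scale (17.7-fold), Eomes by 3.24 (9.42-fold) and Jam2 by 2.25 (4.76-fold). Of 67 neuronal transcription factors 25 fell and 13 rose (29 and 16 over the list alone), with Isl1, a factor of early RGCs, at 9.69 ± 0.08 against 11.43 ± 0.09. Camera gave adjusted p-values of 2.40e-12 and 8.17e-05, with an estimated correlation adjusted p = 0.234 and 0.257. Among 19 pan-RGC genes Isl1 and Ebf1 fell and Nefm and Pou4f3 rose. Igf1, a growth factor gene, fell by 3.50 (11.3-fold) and the neuropeptide gene Tac1 by 2.10 (4.29-fold), among 3 higher and 4 lower of 30 neuropeptide and growth factor genes, with 1 higher without Drd4 replicate 2 or either Thy1 replicate. The Ebf1 call was lost without Thy1 replicate 1 (adjusted p = 0.0796), and the Pou4f3 call in 7 alternatives, such as without Thy1 replicate 1 (0.293) or Drd4 replicate 2 (0.196).

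Of 30 synaptic vesicle and release genes 3 rose in Drd4, namely Cplx1 (2.00-fold), Syt4 (0.69 ± 0.10) and Sv2b (0.83 ± 0.15), and 4 adjusted over the list alone. The list median was 0.18 (camera adjusted p = 0.00263, and adjusted p = 0.257 with an estimated correlation). Sv2b was lost without Drd4 replicate 1 (adjusted p = 0.0684) and Thy1 replicate 2 (adjusted p = 0.0619). Channels changed in both directions, with Kcnd2 (-2.37 ± 0.17) and Kcnip4 (at least 3.84-fold) lower and Kcnq3 (0.85 ± 0.15) among 3 higher of 29 potassium channel genes. Cacna1c rose (1.11 ± 0.15) and Cacna2d3 fell (at least 2.32-fold) among 24 sodium and calcium channel genes. Gabrg3 (1.61 ± 0.17) was among 3 GABA and glycine receptor genes that rose, with Glra3 lower (at least 1.07-fold, lost with the mean of all probe sets at adjusted p = 0.125). Cadherins had 6 of 37 higher and 8 lower, with Pcdh11x (-2.57 ± 0.37) and Cdh10 (-2.44 ± 0.17) lowest, and the Pcdh11x call was lost with robust moderation (adjusted p = 0.0662). Recognition proteins had 10 of 59 higher, led by Dscaml1 (1.90 ± 0.23), and 8 lower. Guidance genes had 7 of 64 higher, among them Robo2 at least 1.61-fold, and 6 lower, among them Unc5d (-1.90 ± 0.15). Adjusted over the list alone, the counts higher and lower were 5 and 3, 2 and 1, 5 and 2, 10 and 10, 13 and 11, and 7 and 11 in that order, and none of these 6 lists passed camera. Cadherins had 3 higher without Drd4 replicate 1 and 5 lower without Thy1 replicate 1, potassium channels had 1 higher without Drd4 replicate 2, and guidance genes had 3 lower without Drd4 replicate 2 or Thy1 replicate 1.

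Microglial genes fell in Drd4 in 13 of 14, with a median of -2.23, and cell cycle genes fell in 8 of 17, with Mki67 at least 2.99-fold lower. Immediate-early and dissociation genes fell in 9 of 20, with Egr1 down 3.69-fold and Fos 3.21-fold, and endothelial and pericyte genes in 5 of 14. Adjusted over the list alone the counts were 14, 15, 12 and 7. Camera adjusted p-values were 2.29e-18, 8.76e-15, 3.67e-11 and 7.03e-06, and with an estimated correlation the adjusted p-values were 0.257, 0.257, 0.308 and 0.257. Without Thy1 replicate 1 they numbered 8, 10, 4 and 4, and without Thy1 replicate 2 they numbered 13, 5, 9 and 4. With robust moderation 7 microglial and 3 vascular genes passed. The horizontal cell list passed with Septin4 and Onecut1 lower (adjusted p = 0.00563, and adjusted p = 0.257 with an estimated correlation). Of 16 Muller glia and progenitor genes Apoe (-3.01 ± 0.41) and Vim (-2.00 ± 0.19) fell and Dkk3 (1.12 ± 0.16) rose, and of 11 cone genes Cngb3 rose (1.33 ± 0.19). Of 6 astrocyte genes Pdgfra fell, at least 1.19-fold, a call lost with the mean of all probe sets (adjusted p = 0.415) and without Drd4 replicate 2 (0.0875) or Thy1 replicate 2 (0.154). Of 7 myelin and oligodendrocyte genes Cnp rose (0.75 ± 0.15), a call lost with the mean of all probe sets (adjusted p = 0.115) and without Drd4 replicate 1 (0.0781), Thy1 replicate 1 (0.0790) or Thy1 replicate 2 (0.0573). None of these 4 lists passed camera. Amacrine, starburst, rod, bipolar and erythrocyte lists had no member past the threshold.

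In all, 995 genes differed between Drd4 and Thy1, 274 higher and 721 lower, and 543 of them by at least 2-fold. The counts without single arrays ran from 666 to 922.

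**Figure D2:**
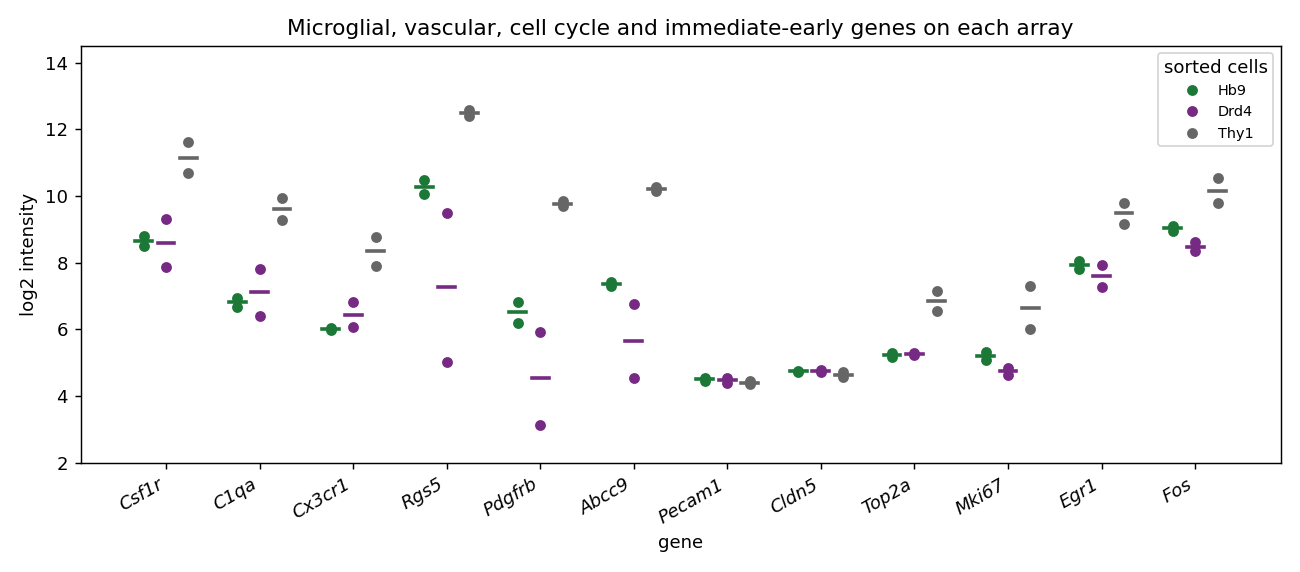
Log2 intensity (vertical axis) of 12 microglial, vascular, cell cycle and immediate-early genes (horizontal axis) on each array, with points for arrays and bars for the means of the 2 arrays of a group. Both Thy1 arrays lie above all GFP arrays for Csf1r, Rgs5 and Egr1, while the endothelial genes Pecam1 and Cldn5 stay below 5 on every array, and the Drd4 arrays stand apart for Rgs5, at 9.50 and 5.01.

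The comparison of Hb9 with Drd4 sets one ooDSGC line against the other. Hb9 cells had 16.3-fold more Col25a1, a transmembrane collagen gene (4.03 ± 0.28), 9.99-fold more Npy (3.32 ± 0.23), more Igf1 (3.17 ± 0.20) and 8.61-fold more Cdh10 (3.11 ± 0.17). Of 2 Col25a1 probe sets 1 passed, and the other differed by 0.03. Cbln4 was 10.9-fold higher. Against Drd4 means at background, Zic2 was at least 9.15-fold, Cdh1 at least 6.52-fold and the chemokine receptor gene Cxcr4 at least 6.25-fold higher. Drd4 cells had at least 22.6-fold more Trhr and at least 4.29-fold more Col24a1 than Hb9 cells, whose values lay at background. Also higher in Drd4 were Nell2 (-3.61 ± 0.24 as Hb9 minus Drd4), Oxtr (-3.27 ± 0.15), Mreg (-3.24 ± 0.34), Kctd4 (-3.00 ± 0.16) and Mmp17 (-2.92 ± 0.18). Cartpt was close in both lines, at 9.33 ± 0.09 and 9.38 ± 0.73 (adjusted p = 0.942).

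Of the ooDSGC genes from the study's own group, Col25a1 and Cdh6 (1.28 ± 0.15) were higher in Hb9 and Mmp17 in Drd4, and adjusted over the list alone the same counts of 2 and 1 were found, not as independent evidence. The median of that list was -0.05 and its mean 0.43, and camera pointed up (adjusted p = 0.76). Of the other ooDSGC genes Calb1 (2.92 ± 0.31) and Cntn5 (1.98 ± 0.18) were higher in Hb9 and Trhr in Drd4, with 2 and 3 adjusted over the list alone. Among 22 markers of other RGC types 7 were higher in Hb9, with Zic1 at 2.73 ± 0.28, and 2, Irx4 and Trarg1, were lower (camera adjusted p = 0.0309, and adjusted p = 0.734 with an estimated correlation). Adjusted over the list alone 11 were higher and 2 lower. Of 67 neuronal transcription factors 17 were higher in Hb9, among them Isl1 (1.93 ± 0.12), and 14 were higher in Drd4, with Neurod6 at least 2.53-fold, or 23 and 15 adjusted over the list alone. Without Hb9 replicate 2 these counts were 10 and 9, and 4 markers of other RGC types were higher in Hb9.

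Of 37 cadherins 8 were higher in Hb9, among them Pcdh11x (2.85 ± 0.37), and 5 in Drd4. Of 59 recognition proteins 9 were higher in each line, with Cntnap5a (2.04 ± 0.19) in Hb9 and Flrt3 (-2.18 ± 0.17) and Cntn3 (-2.11 ± 0.16) in Drd4. Of 64 guidance genes 8 were higher in Hb9 and 4 in Drd4, among them Nrp2 (-2.12 ± 0.16) and Sema5a at least 5.42-fold. Kcnd2 (2.22 ± 0.17) and Kcnip4 (at least 2.62-fold) were higher in Hb9 among 4 higher and 3 lower of 29 potassium channel genes. Tac1 (1.85 ± 0.26) was among 5 of 30 neuropeptide and growth factor genes higher in Hb9, with Fgf1 lower. Adjusted over the list alone the counts higher and lower in Hb9 were 9 and 12, 10 and 13, 10 and 6, 7 and 3, and 6 and 1 for these 5 lists in that order. Of 16 GABA and glycine receptor genes 4 were higher in Hb9, among them Gabra4 (1.49 ± 0.17), and 2 in Drd4, among them Gabrg3 (-1.99 ± 0.17). Of 21 glutamate receptor genes 1, Grin3a (1.88 ± 0.30), was higher in Hb9 and 2 were higher in Drd4. Of 24 sodium and calcium channel genes 1 was higher in Hb9 and 4 in Drd4, among them Cacna1c (-1.04 ± 0.15). Synaptic vesicle genes were the other list past camera, with Cplx1 (-0.93 ± 0.11), Syt4 (-0.92 ± 0.10) and Sv2b (-0.84 ± 0.15) higher in Drd4 (4 adjusted over the list alone, and 1 lower) and a median of -0.05 (adjusted p = 0.0242, and adjusted p = 0.734 with an estimated correlation). Sv2b was lost without Hb9 replicate 1 (adjusted p = 0.108), Hb9 replicate 2 (0.0502) and Drd4 replicate 1 (0.0735). With Hb9 replicate 1 left out, 2 cadherins, 2 recognition proteins, 2 guidance genes and 0 potassium channels passed as higher in Drd4 and 3 guidance genes as higher in Hb9. Without Drd4 replicate 1, 2 cadherins, 3 recognition proteins and 2 guidance genes passed as higher in Drd4, and 8 cadherins did without either Thy1 replicate.

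No member of the microglial, endothelial and pericyte, or immediate-early lists passed between the lines, and 1 cell cycle gene, Birc5, did, at or below background in both. The Birc5 call was lost with the offset of 16 (adjusted p = 0.0546) and without Hb9 replicate 1 (0.125), Hb9 replicate 2 (0.0957) or Drd4 replicate 1 (0.0745). Without Drd4 replicate 1, 2 microglial and 2 vascular genes passed as higher in Hb9, without Drd4 replicate 2, 2 microglial genes as lower, and without either Thy1 replicate 3 cell cycle genes as higher. The median of the microglial list was 0.08 and its mean -0.02, and camera pointed down (adjusted p = 0.658). Lists whose median and mean also differ in sign here are the pan-RGC, astrocyte, cadherin, GABA and glycine receptor, and neuropeptide lists.

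In all, 1113 genes differed between Hb9 and Drd4, 739 higher and 374 lower in Hb9, and 431 by at least 2-fold. With each array centred on its median the split was 539 higher and 431 lower. Without Hb9 replicate 1, Hb9 replicate 2 or Drd4 replicate 1 the count was 411, 532 or 689.

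Both lines shared many changes against Thy1. In the same direction, 422 genes changed in both, 52 higher and 370 lower, where independent lists would share 9.64 and 23.0. The shared rises include Cartpt, Satb1 and Chrna3 (1.09 ± 0.18 in Drd4), and the shared falls include Ahnak, Aspn, Col3a1, Epas1, Jag1 and Eomes. The falls also include 13 of 14 microglial genes and Pdgfrb, Abcc9, Acta2 and Kcnj8, genes of vessel walls. Other cells in the Thy1 sort are thus not separated from a difference between RGCs. In Hb9 the Pdgfrb call was lost in 5 alternatives and the Abcc9 call in 3. Robust moderation was among them (adjusted p = 0.180 and 0.125 in limma). Their Hb9 log2 differences stayed negative over the alternatives, at -3.58 to -2.18 for Pdgfrb and -2.94 to -2.05 for Abcc9. Of the 422, 385 had no call between Hb9 and Drd4. Across genes the log2 differences correlated at 0.54, against 0.50 in simulations of unchanged groups that share a reference, and their covariance was 0.0856 against 0.0137. The simulations had a mean of 0.25 genes changed in both and at most 2. Unchanged groups with noise drawn separately for each gene give few calls by construction. That count therefore does not show how much of the overlap comes from the shared Thy1 arrays. The 2 Thy1 arrays cannot be divided into separate references of at least 2 arrays, so part of the overlap can come from the shared reference. With single Thy1 arrays as separate references the correlation was 0.281 for Hb9 against replicate 1 and Drd4 against replicate 2, and 0.513 the other way round. Without Hb9 replicate 1, Hb9 replicate 2 or Thy1 replicate 1 the shared count was 198, 242 or 224.

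**Figure D3:**
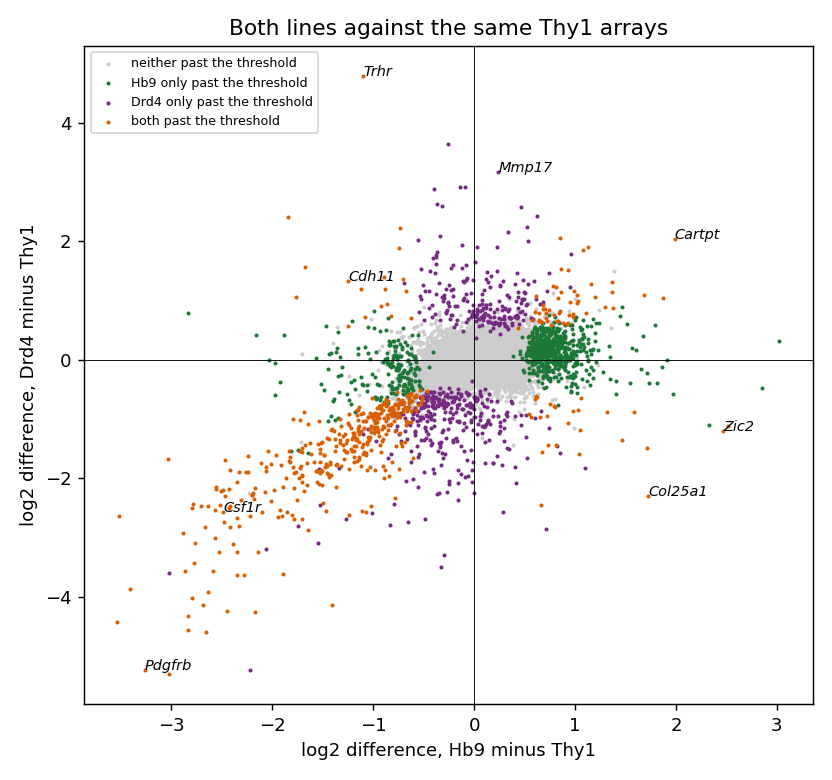
Log2 difference from Thy1 in Drd4 (vertical axis) against that in Hb9 (horizontal axis), with a point for each of 18193 genes coloured by which differences passed the threshold. Most genes past it in both lines lie at the lower left, where 370 genes are lower in both, while Col25a1, Zic2, Trhr and Cdh11 lie in the quadrants of opposite change.

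The mean of both GFP lines differed from Thy1 in 926 genes, 282 higher and 644 lower, and 372 of them by at least 2-fold. Without Thy1 replicate 1 the count was 432.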

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

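The test of a mixture was planned before its value was seen, but the comparison with random offsets was judged void only afterwards. Both lines were compared with the same Thy1 arrays, and 45 genes changed in opposite directions, 27 of them higher in Hb9 and lower in Drd4 and 18 the reverse. All 45 also passed in the comparison of Hb9 with Drd4, which their selection makes nearly certain, so that this is no independent test. The 4 that lead when ranked by the smaller of their changes against Thy1 in size are Col25a1, at 4.03 ± 0.28 as Hb9 minus Drd4 on the log2 scale (adjusted p = 3.51e-05 in limma), Gpc6 at 2.82 ± 0.20 (4.04e-05), Cdh11 at -2.57 ± 0.18 (3.47e-05) and Mreg at -3.24 ± 0.34 (0.000463). Against Thy1, Mreg lost its call with robust moderation in both lines (adjusted p = 0.0504 and 0.0788), in Hb9 without either Hb9 replicate (adjusted p = 0.0763 and 0.0829) or Thy1 replicate 1 (0.112), and in Drd4 without Drd4 replicate 1 (0.0943) or Thy1 replicate 2 (0.122).

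One hypothesis for such genes is that the Thy1 sort holds cells of both kinds, so that its level lies between the lines. Of the 1113 genes that differ between Hb9 and Drd4, 72.2% (804) had a Thy1 mean between the lines. Random offsets gave 89.9% on average and 91.3% at the 95th percentile, because an offset near 0 places Thy1 at the midpoint whether or not the sort is a mixture. By the bound as written a mixture would be excluded. That bound was judged wrong for this reason after the value was seen, and the test decides nothing.

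Probe sets with no gene named carried signal that no comparison used. Tested in limma on the same model among 9160 such probe sets, 199 changed between Hb9 and Thy1 (85 higher and 114 lower), 136 between Drd4 and Thy1 (72 and 64), and 303 between Hb9 and Drd4 (101 and 202).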

How the results depend on the processing

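The count without the genes of the cell type and cell state lists was the 1 alternative chosen after the data were seen, and it gave 1229, 955, 1143, 893 and 395 for the counts named next. The main counts were 1220 for Hb9 against Thy1, 995 for Drd4 against Thy1, 1113 for Hb9 against Drd4, 926 for both GFP lines against Thy1 and 422 for the shared genes. A minimum of 1 on the log2 scale gave 403, 543, 431, 372 and 231, by its own construction. Leaving out dim genes gave 640 for Drd4 against Thy1, 585 for the GFP lines and 252 shared, with fewer genes tested. With the replicate number as a block the counts were 1156, 985, 1030, 892 and 431, and 20 list tests passed. The lone array that remains after 1 is left out was assumed to vary like the other groups. The counts then ran from 315 to 1633, 666 to 922, 411 to 1244, 432 to 1117 and 198 to 480. The lowest came without Hb9 replicate 1 for Hb9 against Thy1, Hb9 against Drd4 and the shared genes, and without Thy1 replicate 1 for the others. Of 20 list tests that passed, 0 passed with an estimated correlation, where 2, 6 and 1 lists had an unadjusted p under 0.05 in the 3 comparisons, and 19 to 24 passed without single arrays. An estimated correlation rests on 3 residual degrees of freedom here, so the lack of passing lists under it decides nothing. Camera has no robust form, so that alternative was not run for lists. Of 197 named calls, 139 passed in every alternative run for single genes in which the gene had a value. Dim genes had none where they were left out, and the minimum of 1 and the added alternative were not counted. The other 58 were lost in at least 1 alternative, most often without Thy1 replicate 1 or Hb9 replicate 1, and then with robust moderation (20). The cause of these losses was not tested. None of 3108 alternative values of these calls changed sign and passed. Probe sets of the same gene did not always agree. Of 133 named calls with over 1 probe set, 105 had every probe set of the same sign, and 0 had a passing one of opposite sign. In Drd4 against Thy1, Epas1, Oxtr, Trhr and Col25a1 each had 1 of 2 probe sets past the threshold. The other differed by 0.44 for Trhr and by -0.04 for Col25a1. Col25a1 also had 1 of 2 in Hb9 against Thy1 (the other at -0.01) and in Hb9 against Drd4 (0.03). Trhr had 1 of 2 in Hb9 against Drd4, with the other at -0.33. Signal over background limits what can be said of dim genes, as 68.2% to 78.9% of genes per array lay above the highest bacterial control.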

Other observations

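The gene families in this paragraph and the next were picked after the data were seen. Of 78 genes of the respiratory chain and ATP synthase, which carry out oxidative phosphorylation in mitochondria, 27 rose in Hb9 against Drd4 (median log2 difference 0.34) and 19 against Thy1 (median 0.27), none fell, and none changed in Drd4 against Thy1. Among them Ndufb7 rose by 1.22 ± 0.21 against Drd4 and by 0.98 ± 0.21 against Thy1. With arrays centred on their medians the counts were 18 and 20, and with quantile normalisation 24 and 11. Without Hb9 replicate 1 both counts were 0 (medians 0.30 and 0.27), and without Hb9 replicate 2 they were 8 and 1. Against Thy1 the count was 1 without Thy1 replicate 1, and against Drd4 it was 7 without Drd4 replicate 1. Over all genes the median was 0.04 in Hb9 against Drd4 and against Thy1. With dim genes left out it was 0.10 against Drd4 and 0.15 against Thy1. The medians of this family are thus not separated from a shift of brighter genes on the Hb9 arrays. The same limit applies in Hb9 to the ribosomal protein genes below. No enrichment test was made. The Hb9 arrays also stood apart in Malat1 and in the 18S ribosomal RNA probe sets, which went both ways as given below, so the preparation of these samples is not separated from a difference between the cells. Cytosolic ribosomal protein genes showed 13 of 46 higher in Hb9 than in Drd4 (median 0.39), with Rpl14 up by 1.26 ± 0.15, but 1 without Hb9 replicate 1, 5 without Hb9 replicate 2, 3 without Drd4 replicate 1 and 8 with arrays centred on their medians. Against Thy1, 1 of them rose in Hb9 (median 0.13) and 3 fell in Drd4 (median -0.24), or 2 in Drd4 with arrays centred on their medians. The Drd4 calls were not kept without Drd4 replicate 1 or Thy1 replicate 2. The Drd4 median without single arrays ran from -0.34 to -0.18.

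Of 12 laminins and nidogens 5 fell in each line against Thy1, among them Nid1 and Lamc1, and 1, Lama3, rose in Hb9, with medians of -0.12 and -0.07. Of 42 collagens 6 fell in Hb9 (3 without Hb9 replicate 2) and 7 in Drd4, and 2 rose in each, and Col4a1 differed by -2.57 ± 0.16 in Hb9 and by -2.54 ± 0.16 in Drd4. Without Hb9 replicate 1 the count of laminins and nidogens in Hb9 was 2, and it was 3 without Hb9 replicate 2 or Thy1 replicate 2. Of 23 biogenic amine receptor genes 3 were higher in Hb9 than in Drd4, namely Htr5b (at least 2.51-fold), Htr1d and Htr5a, and 1, Htr2c, was higher in Drd4 (at least 2.42-fold), with a median of 0.03. Dach2, a relative of genes of retinal determination, was 4.53-fold higher in Hb9 than in Drd4 (2.18 ± 0.16).

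In what follows the tests of microglia, of all vessel cells and of transcript ends were chosen after their results were seen, those of mural cells, nuclear RNAs and unnamed probe sets before. A bootstrap spread for list medians, counts of calls among unnamed probe sets and a count of endothelial genes at background were added after the values were seen. By the bounds as written both sources for mural genes would have been excluded. Microglial genes were lower in both GFP lines. A shift of all genes of that brightness is argued against, since the median nearer to 0 was -2.23, with 10000 random lists of like brightness no lower than about -0.09 at their 2.5th percentile. More microglia in the Thy1 sort is a candidate source. A varying admixture moves its genes together, and at least 85.7% of the 14 genes differed in the same direction between the replicates of every group. Thy1 replicate 1 had the higher Csf1r (11.61 against 10.69) and Ctss (12.03 against 11.38). No list gene is in another list, a sort for GFP and Thy1 could remove such cells, and a change of state in microglia was not tested.

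Mural genes, those of pericytes and vessel muscle, were lower in both lines too, with medians over 5 genes of -2.01 in Hb9 and -2.38 in Drd4. In limma, Rgs5 did not pass in Hb9 (adjusted p = 0.227), and Cspg4 passed in neither Hb9 nor Drd4 (adjusted p = 0.0529 and 0.0935). The Pdgfrb call in Hb9 was lost in 5 alternatives. Vessel fragments of all cell types would also lower endothelial genes, whose median was -0.01 in Hb9 (bootstrap -0.43 to 0.13) and -0.13 in Drd4 (-0.52 to 0.11). Both fall short of the -1 set for this source and lie above the -0.5 set against it, in Hb9 with the whole range and in Drd4 without it. Of these 9 genes, 5 had means at or below the background reference in all 3 groups. They thus gave no signal of such fragments on the Thy1 arrays, and whether their probe sets can detect them was not tested. Above the reference, Flt1 fell in Hb9 (-0.98, adjusted p = 0.00917 in limma) and in Drd4 (-1.06, adjusted p = 0.00377). Kdr, Esam and Egfl7 did not pass in either line. This source is left open because these genes disagree. A second list of 10 mural and fibroblast genes had a median of -0.36 in the comparison nearer to 0, outside random lists, or -0.33 in Hb9 and -0.21 in Drd4 without Abcc9, but its range of -0.87 to -0.14 holds the bound of -0.5, and several of its genes lie near the background reference. More mural cells and vessel fragments therefore both stay open, and cannot be told apart from a difference between the RGCs, which was not tested. The Thy1 sort was gated on Thy1, which could remove such cells. Rgs5 was at 12.39 and 12.58 on the Thy1 arrays, at 10.47 and 10.06 on the Hb9 arrays and at 9.50 and 5.01 on the Drd4 arrays.

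The nuclear RNA Malat1 stood at 8.53 and 9.05 on the Hb9 arrays, against 10.64 to 11.19 on the others, and the 5' probe set of 18S ribosomal RNA read 1125 and 1071 there against 2457 to 3262. The 3' probe set of 18S went the other way, at 9.97 and 9.82 on the log2 scale against 8.91 to 9.76. Less nuclear RNA is argued against, since the median of 9 other nuclear RNAs differed by -0.0126, within random lists and far from the -0.5 it needs. For unannotated transcripts as a class, the bound as written argues only against a fall of the median by the size it sets. Unnamed probe sets differed from named ones of like brightness by -0.0332 (bootstrap -0.0382 to -0.0287), short of the -0.1 it needs and within the -0.05 set against it. How many of them lie at background, where a fall would hardly show, is not given here. The median therefore does not settle whether unannotated transcripts are lower. The verdict by the bound was for a time set to undecided because of the calls, and was put back to the bound as written when more settings had been seen. Of the unnamed calls 66.7% were lower in Hb9 than in Drd4, against 33.6% of the named calls, and the unnamed share was the higher in every setting tried. Against Thy1 the shares were 57.3% and 47.5%, but 59.0% and 55.9% with quantile normalisation and, the other way round, 66.0% and 73.7% among calls of at least 2-fold. These shares were not tested against each other, and a lower signal of some unannotated transcripts is not excluded by the median. Stronger 3' bias stays open too, because Actb and Gapdh disagree. The lower Hb9 array minus the highest other array was -0.33 for Actb and 0.06 for Gapdh. The cause may lie in the cells or in the preparation of the Hb9 samples, and no biological explanation was tested.

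The Y-linked gene Eif2s3y read 3.42 in Hb9 replicate 2 against 7.27 to 8.61 on the other arrays, and Kdm5d read 3.58 against 5.47 to 5.77. Xist read 10.34 to 11.18 on all arrays. Sex is not given in the labels.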
